A study of Escherichia coli with 6 samples.

How the data were processed

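Total RNA of Escherichia coli K-12 W3110 was compared with total RNA of a luxS mutant on 6 Agilent oligonucleotide arrays, each read in the Cy5 and the Cy3 channel. Per the labels' protocols, an overnight culture was diluted to an OD600 of 0.02 in LB with 0.8% glucose, grown at 30 °C to an OD600 of 1, and kept for 30 min without H2O2, with 10% H2O2 or with 30% H2O2 (v/v). The labels do not give the strength of the H2O2 stock. RNA came from 5 ml of culture, and about 10 µg of it was turned into Cy5- or Cy3-labelled cDNA. Each array carried wild type and luxS mutant RNA of the same dose. Each of the 3 doses had 2 arrays, labelled as biological replicates. On replicate 1 in 10% H2O2 the labels give Cy5 to the luxS mutant, and on the other 5 arrays they give Cy5 to the wild type.

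The scanner files give, per the file headers, the mean intensity of each spot and the median intensity of its local background in both channels, background-subtracted and dye-normalized intensities, a log10 ratio of Cy5 to Cy3, and flags. Per the labels these values were made with Agilent Feature Extraction 9.5.3.1. The deposited series table holds the log10 ratio of the scanner file. Compared feature by feature, the table equalled that ratio for replicate 1 in 10% H2O2 (slope 1) and its negative for the other 5 arrays (slope -1), so that by the labels each column is luxS over wild type. The median of each table column was 0. The files of the 10% H2O2 arrays lack the parameter block and hold numbers rounded to 3 significant digits. Per the file headers and names, the arrays sat on 2 slides. The untreated arrays were on one of them, scanned in 1 pass. All 4 treated arrays were on the other, and the 30% H2O2 arrays were scanned in 2 passes. Treatment therefore cannot be separated from slide in any comparison with the untreated arrays.

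Each array had 15744 features, of which 11494 were not controls. They held 10691 probes, 4286 for K-12, 3995 for the strain O157:H7 and 2410 for the strain CFT073. Strains were told apart by the systematic names in the files. Symbols were taken from a table of the MG1655 assembly ASM584v2, in which 4116 of the K-12 probes had their locus tag and 170 did not. The table gave another symbol than the files for 458 probes. Probe positions are those of the files, which name no genome build.

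Mean intensities were corrected against the local background by normexp with an offset of 50, and Cy5 to Cy3 log2 ratios were centred within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. For comparisons between doses the mean log2 intensities of the arrays were then brought to one distribution (Aquantile). Control spots and spots with an outlier flag were left out, and spots of one probe were averaged. Replicate 1 in 10% H2O2, on which the dye term below depends, had 311 flagged features, and the other arrays had between 37 and 79. Probes passed when well above background on both arrays of at least 1 of the genotype and dose groups. One probe, that of highest mean intensity, stood for each of 4261 K-12 loci, 24 of which had more than 1 probe. Probes for other strains entered the normalization and were not tested.

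Genotype ratios, labelled luxS over labelled wild type, were fitted with limma (lmFit and eBayes) over all 6 arrays, with one ratio per dose and one dye term per probe. The dye term could be estimated only from the 10% H2O2 pair, whose dyes are opposite. Disagreement between those 2 arrays therefore enters the dye term, and the 2 residual degrees of freedom come from the untreated and the 30% H2O2 pairs (6.82 in all after moderation). A second fit took one common ratio for all doses, with 4 residual degrees of freedom. It kept the dye term, so the array whose dyes are opposite to those of the other 5 is fitted exactly. That array weighs as much in the common ratio as the other 5 together. Differences between doses in the genotype ratio were contrasts of the first fit. Dose effects within a genotype came from limma's separate-channel fit of the 12 channels, with an intraspot correlation of 0.673 and 5 residual degrees of freedom; 86 genes with a left-out spot were excluded there, which left 4175. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene passed at an adjusted p under 0.05. A comparison of 2 arrays with 2 cannot reach that level in an exact permutation test, where the smallest two-sided p is 0.333, so all tests rest on limma's pooled spread.

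Also, 25 gene lists fixed before the data were examined were tested against all other genes with limma's camera, at a preset correlation of 0.01 and again with the correlation estimated, adjusted over the lists within a comparison. With an estimated correlation camera takes the residual degrees of freedom of the fit. These are 2 for the ratio at each dose, 4 for the common ratio and 5 for the channels. That form of the test thus has little power here, and a list that does not pass it is not shown to be unchanged. Members past the threshold were counted adjusted over all genes and adjusted over the list alone. The members oxyS, tisB, ecnB, cpxP, rpmH, rpmJ and hokB were not tested.

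Genes were named by a rule set before the data were examined. It names luxS on every array, then, per comparison, up to 12 higher and 12 lower genes of largest fold among those that passed and lay on the same side on both arrays of the dose. With fewer than 5 passing genes it adds the 6 higher and 6 lower genes of smallest unadjusted p, and it allows up to 4 members of a described list, those of largest fold, and any member of the lists for AI-2 and for the neighbourhood of luxS. The text names some of the genes the rule allows. Each gene named for a single dose or a dose comparison over both genotypes lay on the stated side on both arrays of its dose, and each one named for a difference of ratios had its labelled ratio beyond both arrays of the other dose on both arrays. Of the genes named for the common ratio, udk and fldA lay on the stated side on all 6 arrays and yhaK on 5. The genotype comparisons, their differences between doses and the dose comparisons within a genotype were planned. The dose comparisons over both genotypes were added once luxS had been seen to contradict the labels on 4 arrays, because a mean of both channels does not depend on which one holds the mutant.

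The steps were tested on simulated data, in which 200 of 4175 genes were changed. The spread of the ratios was that left by the fit, which rests on the untreated and 30% H2O2 pairs. The disagreement of the 10% H2O2 pair thus did not enter it. Genes were drawn independently and no slide difference was put in, so the simulation says nothing about either. For the genotype ratio in 10% H2O2, 92% of the genes changed by 1 on the log2 scale and 100% of those changed by 2 were called, with 8 calls among 3975 unchanged genes. For the genotype ratio without H2O2 these values were 51%, 100% and 16, and in 30% H2O2 they were 42%, 100% and 6. For the difference of the ratio between 30% H2O2 and none they were 44%, 98% and 3, and for 30% H2O2 against none over both genotypes 43%, 98% and 5. Simulations with no change gave 0 calls for the ratio in 10% H2O2 and 0 for 30% H2O2 against none. The number of arrays limits the precision.

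Alternatives set before the data were examined were no background subtraction, Agilent's processed intensities, the deposited table's ratios, no filter, a filter on all 12 channels, the mean over a gene's probes, every probe by itself, no dye term, no between-array or a quantile normalization, a trended and robust variance, a replicate block, only the 4 arrays of the doses compared, each array left out in turn, and an estimated correlation for the lists. Alternatives chosen after seeing the data were genotypes turned on the 4 arrays where luxS contradicts the labels, the ratio in 10% H2O2 from those arrays alone, Aquantile over K-12 probes alone, and only the genes brighter than the 95th percentile of probes for other strains. Figures were drawn with matplotlib 3.10.9.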

Results

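Transcript levels were measured in E. coli K-12 W3110 and in a mutant of luxS, the gene of the enzyme that makes the precursor of the signal molecule AI-2. The labels give 2 variables, genotype and H2O2 dose, so the comparisons address how the genotypes differ at each dose, how each responds to H2O2, and whether the genotype difference depends on the dose. There were 2 arrays without H2O2, 2 in 10% H2O2 and 2 in 30% H2O2, each with both genotypes. Between 99.2% and 100% of the K-12 probes were well above background in each of the 12 channels. Of the probes for genes of other strains, 43.9% to 59.4% were well above background per channel without H2O2 and 84.6% to 94.2% with it. The median absolute difference between replicate log2 ratios was 0.235 without H2O2, 0.492 in 10% H2O2 and 0.314 in 30% H2O2.

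**Figure D1:**
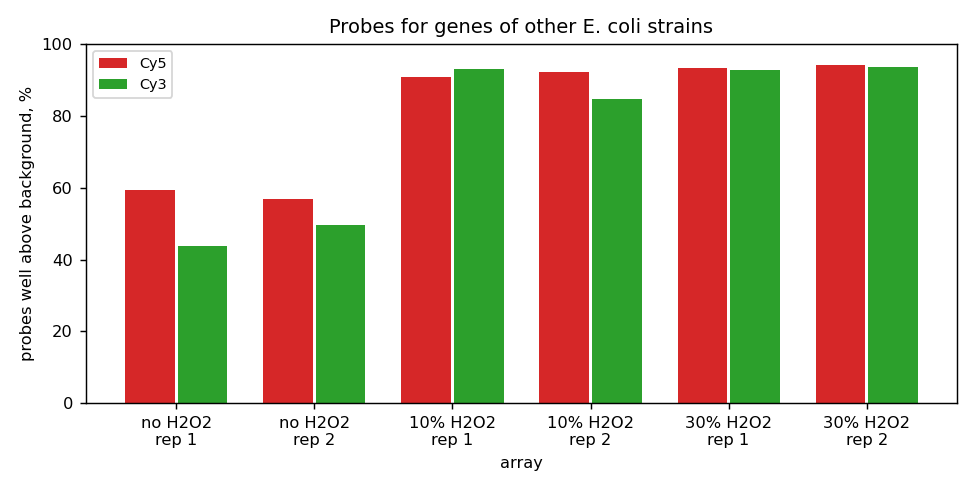
Percent of the 6405 probes for genes of other E. coli strains that were well above background (vertical axis), in the Cy5 and Cy3 channel of each array (horizontal axis). The 4 untreated channels lie between 43.9% and 59.4% and the 8 treated ones between 84.6% and 94.2%.

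The luxS transcript (b2687, probe at 2812508 to 2812567 of the chromosome in the files' coordinates, build not named) was examined first, since it should be low in the mutant. The labels do not say which part of luxS is altered. On replicate 1 in 10% H2O2, where the labels give Cy5 to the mutant, its log2 Cy5 to Cy3 ratio was -4.67. On replicate 2 in 10% H2O2, where they give Cy5 to the wild type, it was 6.28. On both arrays luxS was therefore low in the library labelled luxS. On the other 4 arrays the labels also give Cy5 to the wild type, but luxS was low in Cy5. The log2 Cy5 to Cy3 ratio was -5.08 and -4.11 without H2O2 and -5.89 and -6.02 in 30% H2O2. The labels and the luxS signal thus disagree on 4 of 6 arrays. For these, directions are given for the library labelled luxS (Cy3, high luxS signal) against the library labelled wild type (Cy5, low luxS signal). With the genotypes turned on these 4 arrays, each ratio within the untreated or the 30% H2O2 arrays keeps its size and p-value and takes the opposite sign.

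**Figure D2:**
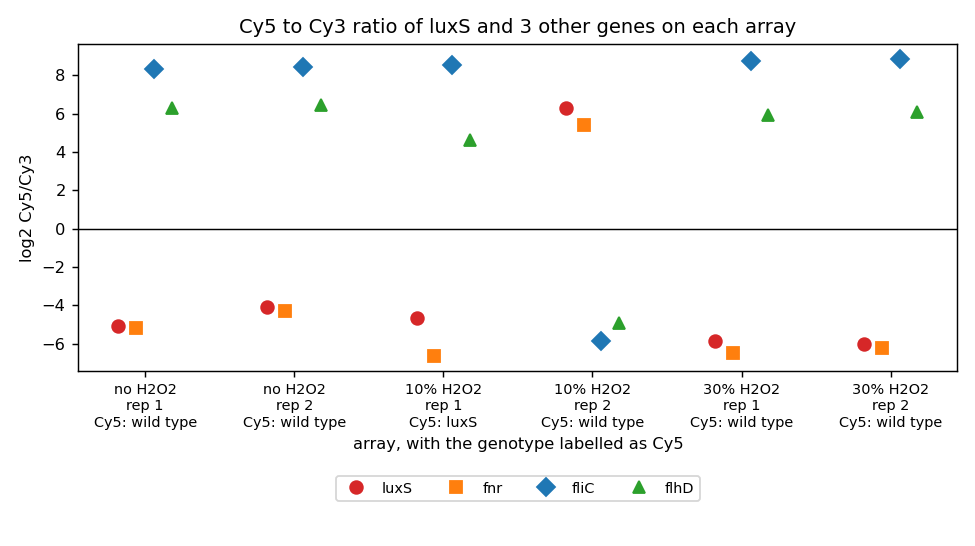
Log2 Cy5 to Cy3 ratio (vertical axis) of luxS, fnr, fliC and flhD on each of the 6 arrays (horizontal axis, with the genotype the labels give to Cy5); each point is 1 array. luxS lies at -5.08 and -4.11 without H2O2, at -4.67 and 6.28 in 10% H2O2 and at -5.89 and -6.02 in 30% H2O2, and fliC lies on the side opposite to luxS on each array.

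In 10% H2O2, where luxS and the labels point the same way, 370 of 4258 genes differed between the luxS mutant and the wild type, 202 higher and 168 lower in the mutant. Fitted from the 10% H2O2 arrays alone, with no dye term, the count was 219. luxS itself was lower by a log2 ratio of -5.48 ± 0.25 (SE, n = 2 arrays; adjusted p = 3.01e-05). The genes with the largest ratios upwards were of flagella and chemotaxis or of their regulation by cyclic di-GMP. The log2 ratio was 7.44 ± 0.25 for cheA, 7.19 ± 0.17 for fliC, which encodes flagellin, 6.95 ± 0.21 for tsr and 6.94 ± 0.20 for cheY. For pdeH it was 5.86 ± 0.36 and for ycgR 5.78 ± 0.35. The adjusted p of these 6 genes lay between 5.89e-06 and 0.000123. The SE and adjusted p at this dose rest on the spread of the untreated and 30% H2O2 pairs. They do not measure the spread of the 2 arrays in 10% H2O2. On those arrays the labelled luxS over wild type ratio was -4.67 and -6.28 for luxS, and 8.52 and 5.87 for fliC. Among the lower genes, fnr, the gene of the regulator of anaerobic respiration, had a log2 ratio of -6.02 ± 0.24 (adjusted p = 1.85e-05). Its neighbour uspE had -5.19 ± 0.26 and the nearby ttcA -4.79 ± 0.22. The C4-dicarboxylate carrier gene dcuA had -4.92 ± 0.31. The nitrogen-limitation genes amtB, nac and astC had -4.79 ± 0.33, -4.16 ± 0.40 and -4.18 ± 0.44. The anaerobic genes nirB, frdB and grcA had -3.95 ± 0.33, -3.27 ± 0.26 and -3.25 ± 0.19. The adjusted p of these 9 genes was at most 0.00148.

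Of the 25 gene lists, 10 passed in 10% H2O2 at the preset correlation of 0.01 (camera). None of them passed with an estimated correlation, where their adjusted p lay between 0.525 and 0.657. For the ratio at each dose that test has 2 residual degrees of freedom, so not passing it says little about a list. The list of flagella and chemotaxis was higher in the mutant in 52 of 54 members (53 adjusted over the list alone), with a median log2 ratio of 4.96 and an adjusted p of 5.14e-72, against 0.525 with an estimated correlation. CRP-dependent sugar use had 21 of 45 members higher (28 adjusted over the list alone; adjusted p = 7.3e-14), with lamB at 3.84, treB at 2.97 and malE at 2.59. Aerobic respiration and ATP synthase had 11 of 34 members higher (12 adjusted over the list alone; adjusted p = 2.2e-06). The tricarboxylic acid cycle had 9 of 21 higher (9 adjusted over the list alone; adjusted p = 1.96e-05), with sdhD at 2.53, and 2 further members were lower adjusted over the list alone. Ribosomal proteins had 6 of 52 higher (6 adjusted over the list alone; adjusted p = 0.000213). For Isc iron-sulfur assembly 0 of 10 members passed, also adjusted over the list alone, while the list as a whole was higher (adjusted p = 0.00596). Anaerobic respiration and fermentation had 16 of 36 members lower (24 lower and 1 higher adjusted over the list alone; adjusted p = 1.9e-11). Iron uptake had 7 of 37 lower (17 lower and 1 higher adjusted over the list alone; adjusted p = 2.2e-06), with feoB at -2.80 and cirA at -1.79. The OxyR regulon, which answers to peroxide, had 8 of 21 lower (11 lower and 1 higher adjusted over the list alone; adjusted p = 0.00136). Its member mntH had a log2 ratio of -2.28 ± 0.25 (adjusted p = 0.00168), and without replicate 1 in 10% H2O2 its ratio was -1.59 (adjusted p = 0.057). Acid resistance had 5 of 19 lower (7 adjusted over the list alone; adjusted p = 0.00187), with gadX at -2.95.

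The other 15 lists did not pass in 10% H2O2, with adjusted p between 0.0589 and 0.782. They were AI-2 synthesis, transport and response, the luxS neighbourhood, SoxRS, SOS, RpoS general stress, heat shock, envelope stress, curli with cellulose and type 1 fimbriae, colanic acid, methionine, cysteine, the synthesis of histidine with tryptophan, branched-chain amino acids and arginine, glycolysis, toxin-antitoxin, and metal homeostasis. With no dye term the cysteine list came to pass (adjusted p = 0.0424). In the AI-2 list luxS and qseB passed. The log2 ratio of qseB was -1.30 ± 0.18 (adjusted p = 0.00503), and without replicate 1 in 10% H2O2 it was -1.12 (adjusted p = 0.0593). In the luxS neighbourhood luxS was the only one of 11 genes to pass; adjusted over the list alone, 3 more were higher. The largest of the other ratios in that list was that of emrA, 0.72 ± 0.18 (adjusted p = 0.0583). Leaving out a 30% H2O2 array cannot change this ratio, since each dose has its own. emrA passed with Agilent's processed intensities (0.8825, adjusted p = 0.049) and with the deposited ratios (0.8836, adjusted p = 0.0491).

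Without H2O2, 321 of 4259 genes differed between the libraries, 195 higher and 126 lower in the library labelled luxS; with the genotypes turned these are 126 higher and 195 lower. The count was 208 without replicate 1 of the untreated arrays, 509 without either 10% H2O2 array and 841 without either 30% H2O2 array. Without either 10% H2O2 array the dye term was dropped, so that count also comes from another model. With no dye term on all 6 arrays it was 411. The luxS transcript itself was higher in the library labelled luxS, by a log2 ratio of 5.40 ± 0.35 (n = 2 arrays, adjusted p = 0.000222). The library labelled luxS was lower in the chemotaxis genes cheY (-9.07 ± 0.28), cheW (-8.43 ± 0.48) and tar (-7.51 ± 0.32), in fliC (-7.06 ± 0.23) and in flhD (-6.55 ± 0.24), which encodes part of the master regulator of flagella. cheA was also lower there, where it was not well above background, so no fold is given. The fitted ratios are corrected by the dye term, which comes from the 10% H2O2 pair alone. For luxS and fliC they lie outside the values of both untreated arrays. Those values were 5.08 and 4.11 for luxS, and -8.33 and -8.45 for fliC. Higher in the library labelled luxS were uspE (6.63 ± 0.37), narK (6.61 ± 0.52), uspF (5.98 ± 0.45), narG (5.29 ± 0.29), nirB (4.97 ± 0.47), grcA (4.75 ± 0.27), ynaJ (4.68 ± 0.36), frdA (4.62 ± 0.42) and dcuC (4.28 ± 0.41). The adjusted p of the named genes other than luxS lay between 3.52e-05 and 0.00136.

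Without H2O2, 8 lists passed at the preset correlation and none with an estimated one, where their adjusted p lay between 0.861 and 0.863. Flagella and chemotaxis were lower in the library labelled luxS in 49 of 54 members (52 adjusted over the list alone; median -4.91; adjusted p = 1.48e-57). Anaerobic respiration and fermentation had 24 of 36 members higher and 1 lower (25 and 1 adjusted over the list alone; adjusted p = 2.71e-21). Acid resistance had 9 of 19 higher (11 adjusted over the list alone; adjusted p = 3.86e-09), with gadX at 3.17, hdeD at 2.90 and gadE at 2.49. CRP-dependent sugar use had 5 of 45 lower (13 adjusted over the list alone; adjusted p = 5.51e-06), with gatD at -2.42. The lists for colanic acid (3 of 23 members lower; adjusted p = 0.00382) and methionine (1 of 16 lower and 1 higher; adjusted p = 0.0405) were lower as a whole. Those for Isc iron-sulfur assembly (0 of 10 members passed; adjusted p = 0.0368) and the synthesis of histidine, tryptophan, branched-chain amino acids and arginine (1 of 33 higher; adjusted p = 0.0405) were higher as a whole. Adjusted over the list alone, 6 colanic acid genes were lower, 2 methionine genes lower and 1 higher, and 0 members of the last 2 lists passed. With no dye term the Isc list no longer passed (adjusted p = 0.263), and SoxRS (0.00431), RpoS general stress (0.00325), toxin-antitoxin (0.00424), ribosomal proteins (0.000102) and the tricarboxylic acid cycle (0.0292) came to pass.

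In 30% H2O2, 192 of 4261 genes differed, 55 higher and 137 lower in the library labelled luxS; with the genotypes turned these are 137 higher and 55 lower. The count was 400 without either 10% H2O2 array, 679 without replicate 1 in 30% H2O2 and 367 without replicate 2. As above, the dye term was dropped without either 10% H2O2 array, and with no dye term on all 6 arrays the count was 273. The luxS ratio was 6.76 ± 0.35 (n = 2 arrays, adjusted p = 9.21e-05), again higher in the library labelled luxS. Lower in that library were cheY (-8.57 ± 0.28), fliC (-7.47 ± 0.23), flgC (-7.35 ± 0.30), rdcA (-7.01 ± 0.40) and pdeH (-6.89 ± 0.52). Higher were fnr (5.75 ± 0.34), ttcA (5.14 ± 0.31), uspE (4.91 ± 0.37), dcuA (4.74 ± 0.43), amtB (4.56 ± 0.47), glnK (4.53 ± 0.38), ddpX (4.14 ± 0.33), grcA (4.12 ± 0.27) and nirB (4.04 ± 0.47). The adjusted p of these genes lay between 3.55e-05 and 0.00372. As without H2O2, the dye term put the fitted ratios of luxS and fliC outside the values of both arrays. In 30% H2O2 those values were 5.89 and 6.02 for luxS, and -8.73 and -8.86 for fliC. At the preset correlation 14 lists passed, and none did with an estimated one, where their adjusted p lay between 0.516 and 0.639. Flagella and chemotaxis were lower in 51 of 54 members (53 adjusted over the list alone; median -5.97; adjusted p = 7.16e-80). Also lower in the library labelled luxS were CRP-dependent sugar use in 19 of 45 members (adjusted p = 3.53e-16), with lamB at -4.59, malK at -3.57 and treB at -3.45, ribosomal proteins in 8 of 52 (adjusted p = 6.24e-11), with rplP at -2.08, and the tricarboxylic acid cycle in 8 of 21 (adjusted p = 0.000287), with sdhA at -2.12. Anaerobic respiration and fermentation were higher in 8 of 36 members (adjusted p = 6.15e-13). Adjusted over the list alone, these counts were 29, 21, 10 and 13. Of the other 9 lists that passed, those for iron uptake (adjusted p = 1.13e-07), heat shock (2.14e-05), acid resistance (0.0258), the OxyR regulon (0.0306) and the SoxRS regulon (0.0344) were higher, and those for aerobic respiration (3.38e-06), cysteine (0.0145), methionine (0.0171) and colanic acid (0.0172) were lower. Among their members 2 of 37 iron uptake and 3 of 19 acid resistance genes were higher, 4 of 34 aerobic respiration and 1 of 23 colanic acid genes were lower, 2 of 34 cysteine genes were lower and 1 higher, and 0 passed in the other 4 lists. With no dye term the SoxRS (adjusted p = 0.0636) and methionine (0.0542) lists no longer passed and envelope stress (0.0307) came to pass.

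**Figure D3:**
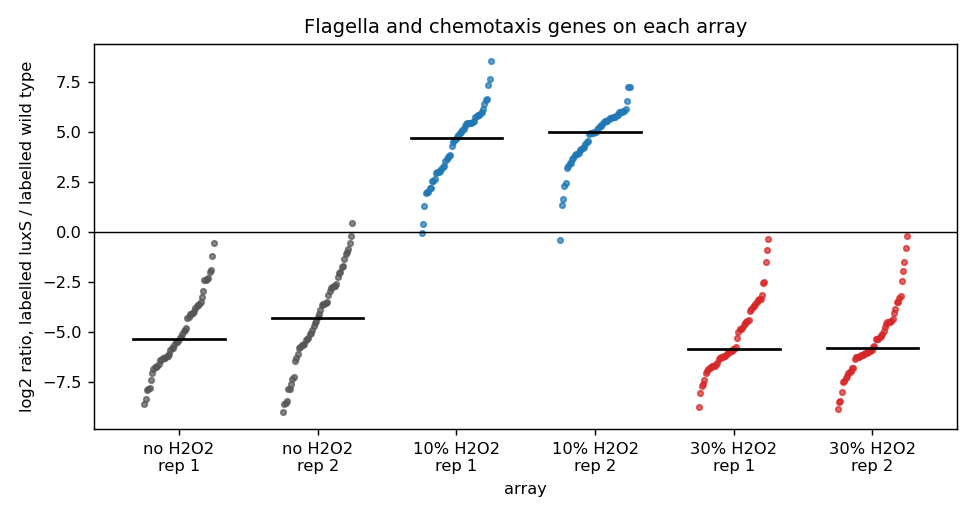
Log2 ratio of labelled luxS over labelled wild type (vertical axis) for the genes of the flagella and chemotaxis list on each array (horizontal axis); each point is 1 gene and the black bars are medians. The medians lie at -5.37 and -4.28 without H2O2, at 4.71 and 5.02 in 10% H2O2 and at -5.85 and -5.81 in 30% H2O2; with the genotypes turned on the untreated and 30% H2O2 arrays all 6 are positive.

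**Figure D4:**
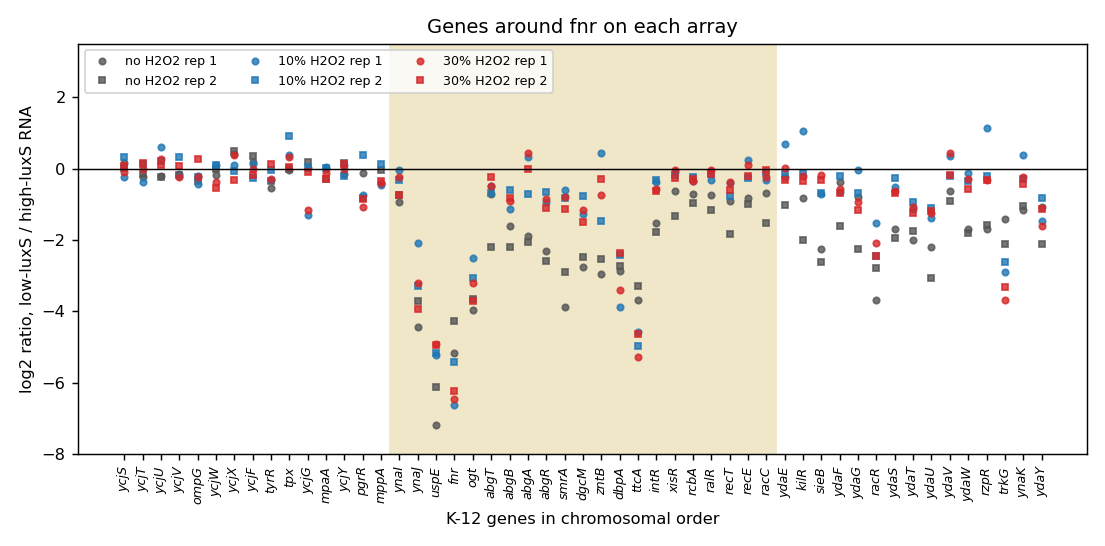
Log2 ratio of the RNA low in luxS over the RNA high in luxS (vertical axis) for K-12 genes in chromosomal order (horizontal axis); each point is 1 gene on 1 array. The shaded genes, 21 in a row from ynaI to racC, were lower by over 0.5 in the RNA low in luxS on both untreated arrays, with a median of -2.20 there (52.4% were well above background in that RNA, so the floor limits some ratios), -0.67 in 10% H2O2 and -0.73 in 30% H2O2.

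With one common genotype ratio over all 6 arrays as labelled, limma called 0 of 4261 genes, while 324 had an unadjusted p under 0.05. The smallest p belonged to genes such as udk (log2 ratio 0.64), fldA (0.57) and yhaK (-0.88), each with an adjusted p of 0.618. Tested one by one, 118 probes passed, probes for other strains included. Turning the genotypes on the 4 arrays made 165 genes pass, 94 higher and 71 lower in the RNA low in luxS. As labelled, the lists for the luxS neighbourhood (adjusted p = 0.0296), Isc iron-sulfur assembly (0.000191) and flagella (0.0283) passed at the preset correlation and had an adjusted p of 0.995 with an estimated one; with no dye term the luxS neighbourhood (0.143) and Isc (0.0559) no longer passed and 10 other lists came to pass. With the genotypes turned the flagella list had 49 of 54 members higher in the RNA low in luxS, with an adjusted p of 4.71e-89, and of 0.0687 with an estimated correlation.

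Whether the genotype ratio depends on the dose was tested as a difference of ratios. The untreated arrays lie on another slide than the treated ones. Any difference of ratios from none is therefore one between slides as well as doses. Between 30% H2O2 and none, where both pairs of arrays carry the same dyes, 265 of 4259 genes differed, 75 upwards and 190 downwards for labelled luxS over labelled wild type (75 downwards and 190 upwards with the genotypes turned). This count was 137 with no dye term and 461 with a replicate block. The ratio of the nitrogen-limitation genes glnK, astC, nac, astA, ddpX and glnG differed by 7.49 ± 0.38, 6.82 ± 0.62, 6.67 ± 0.57, 6.17 ± 0.77, 4.49 ± 0.33 and 3.67 ± 0.36 on the log2 scale. The nitrate respiration genes narK, narG, narH and napF differed by -5.41 ± 0.52, -4.38 ± 0.29, -3.57 ± 0.29 and -4.06 ± 0.49. Flagellar genes went both ways, with fliE at -5.15 ± 0.36 and cheZ at 4.13 ± 0.28. Further members of described lists were ndh (2.63 ± 0.35), gadC (-2.94 ± 0.34) and cirA (2.06 ± 0.27). The adjusted p of these genes lay between 0.00133 and 0.0117. Of the lists 17 passed at the preset correlation, with an adjusted p between 0.47 and 0.716 when the correlation was estimated. Among them were anaerobic respiration with 1 member up and 12 of 36 down (adjusted p = 6.31e-08), aerobic respiration with 1 up and 10 of 34 down (adjusted p = 5.56e-05), ribosomal proteins with 9 of 52 down (adjusted p = 1.71e-05), acid resistance with 6 of 19 down (adjusted p = 1.71e-05) and iron uptake with 5 of 37 up and 4 down (adjusted p = 1.42e-05).

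The ratio in 10% H2O2 differed from that without H2O2 in 358 of 4256 genes as labelled, 154 upwards and 204 downwards, and from that in 30% H2O2 in 430 of 4258. The first count was 555 without replicate 2 in 10% H2O2 and 773 without either 30% H2O2 array, and the second 867 without replicate 2 in 10% H2O2, 816 without replicate 1 in 30% H2O2 and 770 without replicate 2. These comparisons set arrays on which luxS follows the labels against arrays on which it does not. As labelled, luxS differed by -10.88 ± 0.43 between 10% H2O2 and none (adjusted p = 1.03e-05), and fliC by 14.25 ± 0.29. With the genotypes turned these differences were -0.07 (adjusted p = 0.927) and 0.13 (adjusted p = 0.79), and 163 genes differed, 100 upwards and 63 downwards, while 0 genes differed between 30% and 10% H2O2, where 341 had an unadjusted p under 0.05. narK was lower in 10% H2O2 as labelled, by -7.36 ± 0.64, and higher with the genotypes turned, by 5.85 (adjusted p = 0.0139).

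The effect of H2O2 was compared over both genotypes, which does not depend on the labels. The untreated arrays lie on another slide than the treated ones, so each of these differences is between slides as well as doses. Both doses share the untreated arrays, so part of any likeness between them comes from those arrays. In 10% H2O2 against none 2659 of 4175 genes differed, and in 30% H2O2 against none 2569 did. The median log2 change over all genes tested was -0.74 in 10% and -0.65 in 30% H2O2, because intensities were scaled over all probes and probes for other strains brightened. With the scaling over K-12 probes alone the medians were -0.11 and -0.08. The split was 575 higher and 2084 lower in 10% H2O2 and 575 and 1994 in 30% H2O2; with K-12 scaling it was 999 higher and 1199 lower, and 946 and 1115, and with no between-array normalization it was 686 and 1077, and 742 and 1111. Changes below are therefore given relative to the median over all genes. The change also went with brightness, with a Spearman correlation of 0.443 between a gene's mean log2 intensity and its change in 30% H2O2 across genes, which are not independent replicates.

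Relative to that median, the largest rises in 10% H2O2 were those of gfcD (7.40), djlB (7.02), eaeH (6.90), yqfE (6.75), cbl (6.48), ymfT (6.17), carA (6.14), hokA (5.99), rspA (5.93) and cmtA (5.92). In 30% H2O2 the same genes rose by 7.0, 6.51, 6.80, 6.47, 5.92, 5.94, 6.49, 5.66, 5.47 and 5.80. The lysine decarboxylase genes cadB and cadA changed by -7.78 and -5.74 in 10% and by -7.69 and -4.62 in 30% H2O2. The change of yhjX was -4.96 and -5.15, that of asr -4.71 and -4.51, and that of gadC -4.39 and -4.36. In 10% H2O2 cfa changed by -4.08, and in 30% H2O2 rmf by -4.32. The SE of these changes lay between 0.22 and 0.57, each was over 2 arrays of a dose and 2 untreated ones, and adjusted p was at most 3.61e-05, and at most 5.17e-05 with K-12 scaling.

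At the preset correlation 8 lists passed in 10% and 12 in 30% H2O2 against none. With an estimated correlation none passed, with an adjusted p between 0.528 and 0.662 for the lists in 10% and of 0.546 for those in 30% H2O2. Acid resistance was lower in 17 of 18 members at both doses, with a median relative to all genes of -2.82 (adjusted p = 2.65e-05) and -2.99 (adjusted p = 1.24e-05). With K-12 scaling 14 members were lower at both doses and 1 was higher in 10% H2O2. The probes of the near-identical gadA and gadB may not tell these genes apart. Iron uptake had 18 of 35 members higher and 5 lower in 10% H2O2 (median 2.05 above all genes; adjusted p = 6e-08), and 19 higher and 4 lower in 30% H2O2 (1.86; adjusted p = 8.26e-08). Among them cirA, fiu and fepA rose by 4.80, 4.48 and 3.96 in 10% H2O2, and feoA changed by -3.61. The OxyR regulon had 10 of 21 members higher and 1 lower in 10% H2O2 (1.24 above all genes; adjusted p = 2.49e-05), and 8 higher and 2 lower in 30% H2O2 (0.77; adjusted p = 0.00302); with K-12 scaling these medians were 1.02 and 0.459. Its member trxC rose by 4.28 and 3.17, sufA by 4.35 and 2.98, and hcr by 4.86 and 4.41, while hcp, the neighbour of hcr in one operon, changed by -1.88 and -1.86. The SoxRS regulon had 6 of 22 higher and 5 lower in 10% H2O2 (adjusted p = 0.0192) and 6 higher and 4 lower in 30% H2O2 (adjusted p = 0.0105), and soxS rose by 4.75 and 4.14. Methionine genes were lower in 13 of 16 members and higher in 1 at both doses (adjusted p = 0.0171 and 0.00748), with metE at -2.98 and -3.58, metA at -2.76 and -3.06 and metF at -2.60 and -2.53. Anaerobic respiration and fermentation had 28 of 36 members lower and 1 higher in 10% H2O2 (adjusted p = 0.00809) and 30 lower in 30% H2O2 (adjusted p = 0.00302), with focA at -4.07 and -3.45. Flagella (adjusted p = 6.49e-05 and 0.00334) and ribosomal proteins (adjusted p = 0.00602 and 0.00137) lay above all genes at both doses, the latter by 0.778 and 0.687, or 0.175 and 0.15 with K-12 scaling. In 30% H2O2 Isc iron-sulfur assembly (adjusted p = 0.006) and heat shock (adjusted p = 0.0432) also lay above all genes, and curli with type 1 fimbriae (adjusted p = 0.0269) and colanic acid (adjusted p = 0.0276) lay below them. Tested with K-12 scaling, the SoxRS list (adjusted p = 0.214 and 0.162) and ribosomal proteins (0.514 and 0.324) no longer passed at either dose, nor did Isc iron-sulfur assembly (0.0803), heat shock (0.403), curli with type 1 fimbriae (0.214) and colanic acid (0.182) in 30% H2O2. The other 6 lists passed at both doses with it, and the synthesis of histidine with tryptophan, branched-chain amino acids and arginine came to pass in 30% H2O2 (0.0374, against 0.0521). Member counts also depend on the scaling: with K-12 scaling anaerobic respiration had 23 of 36 members lower at both doses, with 1 higher in 10% and 2 in 30% H2O2, and methionine 12 of 16 lower in 10% and 11 in 30% H2O2, with 1 higher at each. Iron uptake then had 21 of 35 higher at both doses, with 5 lower in 10% and 3 in 30% H2O2, the OxyR regulon 11 of 21 higher in 10% and 9 in 30% H2O2, with 1 lower at each, and the SoxRS regulon 8 of 22 higher and 4 lower in 10%, and 7 and 3 in 30% H2O2. The AI-2 list did not pass at either dose (adjusted p = 0.371 and 0.327); within one of its operons lsrA rose by 3.78 and 3.26 while lsrC changed by -1.85 and -1.99.

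**Figure D5:**
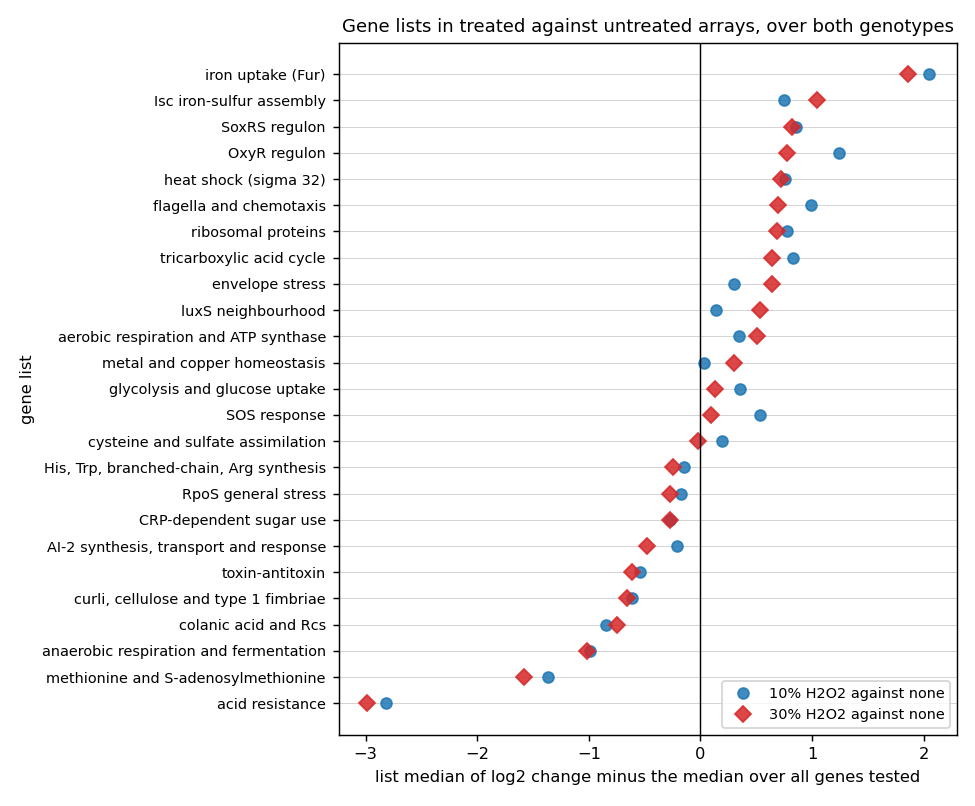
Median log2 change of each of the 25 gene lists minus the median over all genes tested (horizontal axis), over both genotypes, for 10% H2O2 against none (circles) and 30% H2O2 against none (diamonds). Acid resistance lies lowest at -2.82 and -2.99 and iron uptake highest at 2.05 and 1.86; treated and untreated arrays lie on different slides.

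Within the library labelled wild type 2550 genes differed in 10% H2O2 against none, 580 higher and 1970 lower, and 2438 in 30% H2O2, 584 higher and 1854 lower. With K-12 scaling 2003 differed in 10% H2O2, 937 of them higher, and 1879 in 30% H2O2, 923 of them higher. Within the library labelled luxS 2571 genes differed in 10% H2O2, 598 higher and 1973 lower, and 2497 in 30% H2O2, 528 higher and 1969 lower. With K-12 scaling these counts were 2050, of which 940 were higher, and 1972, of which 860 were higher. With no between-array normalization, 661 genes were higher and 977 lower in 10% H2O2 in the library labelled wild type, 758 and 978 in 30% H2O2, 696 and 1025 in 10% H2O2 in the library labelled luxS, and 716 and 1122 in 30% H2O2. Turned, the counts were 2509 and 2497 for the RNA high in luxS, and 2504 and 2438 for the RNA low in luxS.

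The 2 doses share a slide. Over both genotypes 1 of 4175 genes, bdcA, differed between 30% and 10% H2O2, with a log2 change of -2.42 ± 0.30 (adjusted p = 0.0311), while 250 genes had an unadjusted p under 0.05. bdcA no longer passed without either untreated array (-2.42; adjusted p = 0.534), without replicate 1 in 10% H2O2 (-2.14; 0.0611) or without replicate 2 in 30% H2O2 (-2.18; 0.234), nor with Agilent's processed intensities (-2.58; 0.119) or no between-array normalization (-2.39; 0.153), and without replicate 2 in 10% H2O2 153 genes passed. The next genes by p, fis (1.56 ± 0.23) and rhaS (-1.67 ± 0.26), did not pass (adjusted p = 0.0722) and passed without replicate 2 in 10% H2O2 (adjusted p = 0.0156 and 0.0187); rhaS also passed with Agilent's processed intensities (0.0248), and fis among the genes above the 95th percentile of other-strain probes (0.00599). At the preset correlation the lists for the OxyR regulon (adjusted p = 9.22e-05), flagella (0.00209) and glycolysis (0.0224) were lower and Isc iron-sulfur assembly (0.00209) was higher in 30% H2O2, and their adjusted p lay between 0.799 and 0.891 with an estimated correlation. As labelled, 248 genes differed between the doses in the wild type and 209 in the luxS mutant. The first count was 162 without replicate 1 and 165 without replicate 2 of the untreated arrays, 492 without replicate 2 in 10% H2O2 and 159 without replicate 2 in 30% H2O2, and the second was 570 without replicate 2 in 10% H2O2. They were 2 and 0 with the genotypes turned, with 314 and 269 genes at an unadjusted p under 0.05. The flagella list in the library labelled luxS was the only one of 325 planned list tests to pass with an estimated correlation (adjusted p = 0.0306). It sets arrays on which luxS follows the labels against arrays on which it does not.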

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

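The tests of exchanged labels, of a genotype effect that turns with the dose, of a dye bias, of a response to H2O2 and of other choices of dye were chosen after the results were seen; those of single probes and of GC content were chosen before.

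The genotype ratio differed between doses in tests of the difference itself, which brings 3 comparisons here. As labelled, 358 genes differed between 10% H2O2 and none, 265 between 30% H2O2 and none, and 430 between 30% and 10% H2O2. With the genotypes turned on the untreated and 30% H2O2 arrays these counts were 163, 265 and 0. Both comparisons with none are also between slides, while 10% and 30% H2O2 share a slide.

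The luxS transcript was low in the library labelled wild type on those 4 arrays. A dye bias of the luxS probe is argued against by its fitted dye term of 0.808 on the log2 scale, against a ratio of at least 4.11 in size on each of the 4 arrays. By the luxS transcript alone, a genotype effect that turns with the dose cannot be told apart from exchanged labels. The labelled luxS ratio of at least 4.11 is the pattern itself, and the labels do not describe the mutation. Such an effect would have to turn the flagella list as well, in 10% H2O2 and back in 30% H2O2. The median labelled ratios of that list were -5.37 and -4.28 without H2O2, 4.71 and 5.02 in 10% H2O2, and -5.85 and -5.81 in 30% H2O2. It would also have to turn the run of genes from ynaI to racC. Of these 21 genes, 18 were lower in the RNA low in luxS on all 6 arrays, with fnr between -4.27 and -6.63. A lost DNA segment cannot turn with the dose. If this run was lost from one strain, which stays open, these values argue against such an effect for the run. Exchanged labels on the 4 arrays remain a candidate explanation: over K-12 genes other than luxS, their labelled ratios had a mean correlation of -0.677 with those of the 10% H2O2 arrays (8 pairs, from -0.898 to -0.516, across genes). That correlation does not say which arrays are exchanged; the luxS signal alone points to the 4.

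As labelled, the common ratio gave 0 genes. A count of 0 is reached by each of the 31 choices of which dye holds the mutant, whatever the data, so these splits say nothing about chance for it. The highest count among them, 165, came from the choice with the genotypes turned on the 4 arrays, which points to a structure of the samples.

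Probes for genes of other E. coli strains are outside the comparisons made. On average 90.2% of them (SD 3.83, 4 channels) were well above background in 10% H2O2 and 93.4% (SD 0.633, 4 channels) in 30% H2O2, against 52.4% (SD 7.02, 4 channels) without H2O2. In the Cy3 channel the median net signal of negative controls was 52.7 and 53.3 without H2O2 and between 16.1 and 18.5 with it, so the background itself differed between the slides.

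Treated and untreated arrays differed in 2659 of 4175 K-12 genes in 10% and in 2569 in 30% H2O2. The counts were 2198 and 2061 with the scaling over K-12 probes alone, and 1763 and 1853 with no between-array normalization. GC content of the probe is argued against as the cause, since its Spearman correlation with the change in 30% H2O2 was -0.0147. For differences carried by single probes rather than transcripts, the change of neighbouring genes on one strand had a correlation of 0.265, between the bounds set for either answer, against at most 0.0488 in 1000 shuffles of the gene order, 0.0469 for neighbours on opposite strands and 0.719 for the genotype ratio in 10% H2O2. A response to H2O2 cannot be told apart from the slide and its scan, because no untreated array lies on the treated slide. On that slide 1 gene differed between the doses over both genotypes. As labelled, 248 differed in the wild type and 209 in the mutant, and with the genotypes turned 2 and 0 did. Response and slide both stay open, and the differences may hold a part of each.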

How the results depend on the processing

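The turned genotypes, the 10% H2O2 arrays alone, the scaling over K-12 probes and the limit to bright genes were chosen after seeing the data; all other alternatives were set before. Of 2608 values of named genes under 22 alternatives, 2583 kept their direction and their side of the threshold, 11 no longer passed, 11 came to pass and 3 reversed; genes on the untreated and 30% H2O2 arrays were read here as Cy3 over Cy5. Part of this agreement was fixed in advance. The naming rule favours large folds past the threshold. The filter removed none of the 4261 loci, and the mean over probes touched only 24. Turning the genotypes cannot change values over both genotypes. Nor can it reverse the ratios on the untreated and 30% H2O2 arrays or their difference here, since Cy3 over Cy5 is the same either way. Read as luxS over wild type, each of these takes the opposite sign. Leaving out a 30% H2O2 array cannot change the size of the ratio in 10% H2O2. Within 1.5 times of the reported count stayed each count under no background subtraction, Agilent's intensities, the deposited ratios, no filter or the filter on all channels, the mean over probes, quantile normalization, the trended variance and the K-12 scaling. Of 20 list calls for H2O2 over both genotypes, 0 had a median on the other side of all genes under 5 scalings, though with K-12 scaling 6 of 8 in 10% and 6 of 12 in 30% H2O2 still passed.

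With the genotypes turned, the common ratio gave 165 genes, the ratio's difference between 10% H2O2 and none 163 and between the doses 0, and the doses differed in 2 genes in the wild type and 0 in the mutant. Reversed were narK between 10% H2O2 and none (5.85), and luxS (-1.29) and fliC (0.28) between the doses. With the estimated correlation 1 of 136 list calls passed. The few residual degrees of freedom limit that test, so this drop does not show that the other lists are unchanged.

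Tested by probe, with other strains included, counts were 706 without H2O2, 672 in 10% H2O2, 118 for the common ratio, 575 and 474 for its difference from none in 10% and 30% H2O2, 5023 and 4782 for 10% and 30% H2O2 against none in the labelled wild type, 5111 and 5047 in the labelled mutant, 5278 and 5071 over both, and 0 between the doses over both; more probes were tested. Among the 998 genes above the 95th percentile of other-strain probes they were 583 and 522 in the labelled wild type, 583 and 547 in the labelled mutant, 631 and 572 over both, and 112 in the labelled mutant and 8 over both between the doses; fewer genes were tested. Higher and lower then came to 293 and 338 in 10% and 290 and 282 in 30% H2O2 over both.

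With no between-array normalization, 10% H2O2 against none gave 1638 genes in the labelled wild type and 1763 over both (686 higher), and the doses differed in 161 in the labelled wild type and 0 over both. With only the 4 arrays of the doses compared, the ratio's difference between 10% H2O2 and none gave 773, 10% H2O2 against none over both 1735, and the doses 162 in the labelled wild type and 0 over both; fewer arrays were fitted. With no dye term the ratio's difference between 30% H2O2 and none gave 137. From the 10% H2O2 arrays alone, that dose's ratio gave 219. Except for the number of probes, genes or arrays, the cause was not tested.

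Same-numbered arrays' deviations correlated between none and 10%, none and 30%, and 10% and 30% H2O2 by 0.013, 0.0927 and -0.573 in the labelled ratio, -0.013, 0.0927 and 0.573 with the genotypes turned, and -0.12, -0.0631 and 0.402 in mean intensity. The replicate numbers thus do not pair the untreated arrays with the others. With the genotypes turned, ratios of same-numbered arrays in 10% and 30% H2O2 correlated across genes by 0.898 and 0.843. Differently numbered ones correlated by 0.726 and 0.749, and the replicates by 0.671 in 10% and 0.831 in 30% H2O2. For the treated arrays these values go with a pairing if the genotypes are turned, while the labelled deviations do not. The main fits use no such pairing. With a replicate block the ratio's difference between 30% H2O2 and none gave 461 genes and the doses over both 4, with fis and rhaS then passing (adjusted p = 0.0283 each), and emrA passed in 10% H2O2 (0.0409); no other count moved by over 1.5 times.

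With each array left out in turn, counts ranged from 208 to 841 for the ratio without H2O2, 191 to 1054 in 10% and 249 to 679 in 30% H2O2, 280 to 773, 154 to 721 and 430 to 867 for its differences between 10% H2O2 and none, 30% H2O2 and none, and the doses, and, between the doses, 159 to 492 in the labelled wild type, 167 to 570 in the labelled mutant and 0 to 153 over both. The counts against none stayed within 1.5 times, and the common ratio gave 0 each time. Lowest without H2O2 (208) and for 30% H2O2 against none (154) was the fit without untreated replicate 1; in 10% H2O2 (191) it was that without its replicate 1. Leaving out 10% H2O2 replicate 2 gave 867, 492, 570 and 153, and either 30% H2O2 array 841 and 1054. A lone array was assumed to vary like the other groups, with the intraspot correlation of all 6 arrays, and without either 10% H2O2 array the dye term was dropped.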

Other observations

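The test for loss of a DNA segment, the count of low genes past the run and the groups of nitrogen-limitation and NADH dehydrogenase genes were chosen after the values were seen; the test for repression of one operon was chosen before.

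On the untreated arrays 21 neighbouring genes, from ynaI to racC with fnr among them, were all lower in the RNA low in luxS by over 0.5 on the log2 scale on both arrays. The longest such run in 1000 shuffles of the gene order was 6 genes. Shuffling separates neighbouring genes, whose genotype ratios go together (correlation 0.719 on one strand in 10% H2O2). The shuffles thus cannot show how long a run arises from operons alone. The median log2 ratio of the run was -2.20 without H2O2, where the floor limits the ratios of genes not well above background, -0.67 in 10% and -0.73 in 30% H2O2, and 18 of the genes were lower in that RNA on all 6 arrays. The run ends at racC because ydaE, the next gene, was at -0.24 on replicate 1 of the untreated arrays. Of the 22 genes from ydaE to uspF 18 were low by the same bound, against 1 of the next 18, so the stretch reaches beyond the run tested. Repression of one operon is argued against by the strands, with 16 genes on one and 5 on the other. Loss of the DNA segment from one strain is a candidate explanation that stays open: 52.4% of the run's genes were well above background in the RNA low in luxS, just outside the bound of at most 50% set for it, against 95.2% in the other RNA and 99.4% of all K-12 genes in the same channel. Probes for other strains, whose matches to K-12 were not examined, reached 59.4% and 56.8% in that channel, so the flag may not separate absent from weak transcripts. No gene of the run was brighter there than the 95th percentile of those probes, against 28.4% and 27.3% of all K-12 genes; in the other RNA 9.52% of the run was. If the segment were missing, the genotypes may differ by more than luxS, and loss of fnr might lower the genes of anaerobic respiration, neither of which was tested.

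For 15 nitrogen-limitation genes, picked for their values and not tested as a list, the median labelled ratio was negative without H2O2 and positive in 30% H2O2. In what follows, differences from none are also differences between slides. In the library labelled luxS 9 were lower without H2O2 (median -1.97), 12 were lower in 10% H2O2 (median -1.99) and 7 were higher in 30% H2O2 (median 1.95), and in tests of the difference 14 were higher in 30% H2O2 than in none (median 3.79). Between 10% H2O2 and none 1 was lower as labelled (median -0.162) and 14 with the genotypes turned (median -3.72), and between 30% and 10% H2O2 10 were higher as labelled (median 3.88) and 0 differed with the genotypes turned (median 0.407). Of 13 NADH dehydrogenase subunit genes, 7 were higher in the library labelled luxS in 10% H2O2 (median 1.11), 0 differed without H2O2 (median 0.18) and 1 was lower in 30% H2O2 (median -1.55). In tests of the difference 6 of them were lower in 30% H2O2 than in none (median -1.72), 0 differed between 10% H2O2 and none as labelled (median 0.859) and 1 with the genotypes turned, and between 30% and 10% H2O2 8 were lower as labelled (median -2.72) and 0 differed with the genotypes turned.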
